A study of Mus musculus with 5 samples.

How the data were processed

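RNA was measured in pituitaries of mouse embryos at e12.5. The libraries came from 3 control embryos, with both Itgb1 alleles floxed, and 2 littermates that also carried the Pitx1-cre transgene. The labels describe separate biological replicates. Per the labels' protocols, total RNA was depleted of ribosomal RNA with Ribo-Zero, made into strand-specific libraries with ScriptSeq v2 and sequenced on a HiSeq 2000. The submitters' processing notes name Bowtie2, HOMER, edgeR and the mouse build mm9, and give no roles or versions.

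The all-gene table holds a normalized signal per gene region and library that the authors deposited as tags per 10000000 total tags, per the file headers. It lists 21022 regions for 20097 gene symbols, and 171 regions are at 0 in every library. The longest region was kept for each symbol. Every region is listed on the plus strand, so antisense and overlapping genes cannot be told apart. Against the gene positions in the authors' deposited table of changed genes, the start of a region lay a median of 800 bp inside 490 plus-strand genes. For 529 minus-strand genes the median was 400 bp at each end. The regions span introns as well as exons.

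The authors' deposited table of changed genes holds a log2 fold change, 2 columns of linear fold changes (a ratio each), a p-value and a value per genotype. The genotype values were treated as a score because the deposited header gives them no unit, and it does not say which libraries they come from. The adjustment of the deposited p-value is not given in the sources used here.

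The analysis planned before the data were examined was an edgeR count test, with limma if the file held normalized values. It held normalized values, so the test was limma (version 3.58.1, R 4.3.3) with a trend on log2(value + 1), over the 19313 genes with a mean of at least 1. Fold changes are on that scale, which understates changes of low genes. Values were Benjamini-Hochberg adjusted with a threshold of 0.05. All values were whole multiples of 10/11 within 0.01 reads (100.00% of values), as for 11000000 total tags in each library. Reads recovered in this way summed to between 4480809 and 6143263 over the listed genes per library. Count tests on these reads with edgeR 4.0.16 and DESeq2 1.42.0 were alternatives. The quasi-likelihood test of edgeR with TMM factors, added after the data were seen, called 0 genes of 15623, with 513 at an unadjusted p under 0.05. Counting intervals are exact Poisson intervals at 95% and cover counting error only.

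The median log2 change of the tested genes was 0.97, so changes of single genes and lists are given relative to that median. The limma p-values of single genes test the change before that median is taken off, while camera compares a list with the other genes. The 33 gene lists were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, 2-sided, and adjusted over the 33 lists. Camera with an estimated correlation and the fry rotation test were alternatives. The other alternatives were normalization factors, filters, pseudocounts, thresholds and leaving out each library in turn. Leaving out a knockout library leaves 1, which is then assumed to vary like the controls. A covariate for sex was planned if both groups held both sexes, and otherwise an alternative without the genes of the sex-linked list. Library 16 could not be assigned a sex, so that alternative was run (19308 genes). Its tags over 4 Y-linked genes did not exceed its background. That background came from autosomal genes, so this does not show that Y-linked tags were absent. Its Xist was at 204.55, against 2089.09 in control library 10. The main fit kept the sex-linked genes and tested their list. A covariate was added after the data were seen, with control library 10 as the other sex, alone or together with library 16.

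Named genes followed a rule fixed in advance. Itgb1 came first. The rule then took the 10 called genes of lowest p per direction at a mean of at least 20 tags per 10000000, without unnamed models, small RNAs and pseudogenes. With fewer calls it took the 5 of lowest p, named as not past the threshold. For each list it took up to 4 called members, or else the 2 of highest mean level. Genes chosen after their values were seen are named as such. Some genes that the rule takes are not reported here.

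Background was estimated, after the data were seen, from 408 autosomal olfactory and vomeronasal receptor genes. Their tags per kilobase, times region length, were subtracted from each value with a floor of 0. This overcorrects where background is uneven. Fits with background subtracted alone kept a mean of at least 1 (17993 genes). Fits with TMM factors also kept a mean of at least 5 (14629 genes with all libraries), so they differ from the main fit in the filter too. Tests on simulated counts with 200 changed genes, for knockout against control over 19251 genes, recovered 46.3% of genes changed 2-fold, 95.5% at 4-fold and 100.0% at 8-fold with limma, with 1 false call. A simulated list with a log2 change of -1 was called at the preset correlation, and 0 other lists were. Coordinates are mm9 as deposited. No mm9 gene annotation was used here, so exon and intron positions are not given.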

Results

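Gene expression was profiled in the pituitaries of 5 mouse embryos at e12.5, a stage of gestation when the gland is a pouch of dividing progenitors with few hormone cells. The 3 control libraries carried floxed Itgb1 alleles, and the 2 knockout libraries also carried Pitx1-cre, which acts in the oral ectoderm and pituitary. Itgb1 encodes integrin beta 1, the shared subunit of most receptors for extracellular matrix. Values are tags per 10000000 total tags of a library, and levels below are in this unit. The reads recovered over listed genes numbered 5806107, 5445240 and 6143263 in control libraries 9, 10 and 12. They numbered 5507288 in the library labelled Itgb1 KO 13 and 4480809 in the library labelled Itgb1 KO 16, called libraries 13 and 16 from here. The ribosomal precursor Rn45s took 22.2%, 16.8% and 23.5% of all tags in the controls, 14.2% in library 13 and 8.9% in library 16. Libraries of the control group differed from each other by more than counting noise, with a chi-square per degree of freedom of at least 9.1.

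Library 16 stood apart from the other 4. The first principal component held 72.9% of the variance and placed it at 170.2, against 18.7 for library 13 and -113.3 to -6.0 for the controls. Across genes, level followed region length with a Spearman rho of 0.93 in library 16, 0.69 in library 13 and 0.64 to 0.73 in the controls; genes are not independent replicates. Olfactory and vomeronasal receptor genes, which are silent in most tissues, carried 1.50 tags per kilobase in library 16. They carried 0.48 in library 13 and 0.26, 0.40 and 0.16 in the controls.

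**Figure D1:**
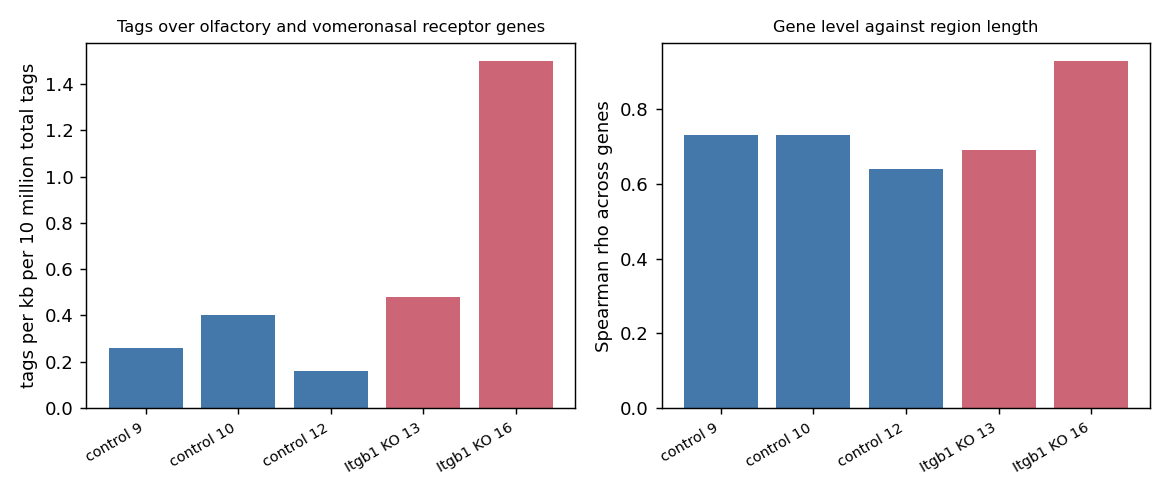
Left, tags per kilobase per 10000000 total tags over receptor genes for each library; right, Spearman rho across genes between level and region length (unitless). Bars are single libraries, blue for control and red for knockout; library 16 is the highest in both, at 1.50 and 0.93.

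The first question was whether the targeted gene was lower in the knockout libraries. Itgb1 (mm9 chromosome 8, 131210354 to 131257479) had a level of 376.7 ± 90.0 (SD, n = 3) in the controls. Library 13 held 446.36 tags per 10000000, above every control, and library 16 held 186.36, below every control. The order of library 13 turned with scaling: with background subtracted and TMM factors, both chosen after the data were seen, the controls were at 414.11, 386.87 and 464.96, library 13 at 292.14 and library 16 at 121.08. The fitted log2 change of Itgb1 was -0.35 (limma, adjusted p = 0.621). Relative to the median gene, which was 0.97 higher, this is a change of -1.32, which the p-value does not test. An exact permutation test over the 10 splits of the libraries, 2-sided, gave p = 0.7, where the smallest possible is 0.1. The region covers the whole gene and the gland also holds cells without Pitx1-cre, so this level does not isolate the deleted part. It does not check the label of library 13.

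No single gene passed an adjusted p under 0.05 between the genotypes. With limma 0 of 19313 genes passed, the lowest adjusted p being 0.0707, and 5636 genes had an unadjusted p under 0.05 where chance gives 966. Of these, 5632 were higher and 4 lower, and the median log2 change of all tested genes was 0.97. The limma p-values of single genes test changes that include this shift. With TMM factors the median was 0.04 and 381 genes had an unadjusted p under 0.05. Counts on the recovered reads gave 0 calls with the exact test and with the quasi-likelihood test of edgeR, and 25 lower genes with DESeq2. The count depended on the library left out: the quasi-likelihood test called 6134 genes without library 13 and 3 without library 16.

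The genes of lowest p among those with higher values included Rnf128, Skint5 and Umodl1, and none passed the threshold. Rnf128 was at 20.9 ± 15.5 (SD, n = 3) in the controls, 56.36 in library 13 and 187.27 in library 16, with an adjusted p of 0.0707 in limma. Umodl1 had a relative log2 change of 1.54. In each of these 3 genes library 16, where level followed gene length, held the highest value. With background subtracted, Skint5 was at 0 in every library, and Rnf128 was at 23.94 and Umodl1 at 69.07 in library 16.

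Among genes with lower values those of lowest p were Ndn, Chga, Islr2, Fgf10 and Cga, and none passed the threshold either. Their adjusted p in limma ran from 0.126 to 0.172. Ndn was at 83.9 ± 7.29 (SD, n = 3) in the controls, 104.55 in library 13 and 10 in library 16. With background subtracted and TMM factors it was at 71.80 in library 13, also below the lowest control at 79.91. Islr2 was at 76.4 ± 5.96 (SD, n = 3) in the controls, 47.27 in library 13 and 20.91 in library 16, below every control in both.

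The hormone gene Cga and the granule protein genes Chga and Scg2 lay below every control in library 13 and, before scaling, within the controls in library 16. Relative to the median gene they were lower in library 16 too, with a median log2 change of -1.12 over the 3 genes in the fit without library 13, where limma called none of them. The median gene was itself 1.28 higher in that fit. With background subtracted and TMM factors, the log2 ratios of the 3 genes to the control mean were -0.33, -0.26 and -0.12 in library 16. They were -5.58, -4.57 and -2.23 in library 13. Chga was then at 63.47 in library 16, below the lowest control at 67.00. Cga (mm9 chromosome 4, 34841828 to 34854623), the alpha subunit shared by the glycoprotein hormones, was at 31.82, 107.27 and 55.45 in the controls, 8.18 in library 13 and 70 in library 16. The 9 reads of library 13 give a 95% Poisson interval of 3.74 to 15.5. Chga (mm9 chromosome 12, 103793979 to 103803237), which encodes the granule protein chromogranin A, was at 69.7 ± 24.6 (SD, n = 3), 9.09 and 74.55. Scg2, which encodes secretogranin II, was at 227.6 ± 94.2 (SD, n = 3) in the controls, 81.82 in library 13 and 234.55 in library 16. Without library 16 the edgeR quasi-likelihood test called these 3 genes alone, all lower, while limma on the same libraries called none (adjusted p = 0.468 for each). With background subtracted and TMM factors also, limma called Chga, Cga and Tshr (chosen after its values were seen), and not Scg2. In the quasi-likelihood test the relative log2 changes were -3.68 for Chga, -3.67 for Cga and -2.22 for Scg2, with adjusted p of 0.00157, 0.00655 and 0.0163. The list of 23 measured pituitary differentiation genes, hormones and lineage factors, had 11 members above and 12 below the median gene and did not pass the camera test (adjusted p = 0.0962). Its median relative log2 change was -0.40 in library 13 and 0.11 in library 16. It passed, lower, without library 16 (adjusted p = 2.7e-08) and without control library 12 (adjusted p = 0.009).

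Taken as a list, progenitor genes lay on opposite sides of the median gene in the 2 knockout libraries. The list of 22 Rathke's pouch genes was lower as a set (camera, adjusted p = 0.00022), with 18 members below the median gene. The call did not hold with an estimated correlation (adjusted p = 0.973). Its median relative log2 change was -1.65 in library 16 and 0.28 in library 13, and the direction turned without library 16 (adjusted p = 0.461). The call was lost with background subtracted and TMM factors (adjusted p = 0.172), and the median in library 16 was -0.88. Dach1 and Eya1, its 2 members of highest level, had relative log2 changes of -0.62 and -0.38. Chosen after their values were seen, the pouch regulators Six6, Lhx3 and Hesx1 lay above every control in library 13, where the median gene was also 0.80 higher on the log2 scale. Six6 was at 114.8 ± 41.1 (SD, n = 3) in the controls, 282.73 in library 13 and 54.55 in library 16, and Lhx3 at 67.0 ± 15.5 (SD, n = 3), 140 and 40. With background subtracted and TMM factors library 13 was closer to the controls. Six6 was then at 193.55 against a highest control of 144.23, Lhx3 at 94.69 against 89.88 and Hesx1 at 41.61 against 28.74. Otx2 and Tbx3, list members from the same later choice, went the other way and lay below every control in library 13. On the subtracted and scaled values Otx2 was at 7.49 there, against a lowest control of 16.29, and Tbx3 at 62.72 against 144.30.

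Cell cycle genes followed the same split. S phase genes (24 measured, 19 below the median gene) had an adjusted p of 0.0041 and G2 and M phase genes (25 measured, 22 below) one of 0.00232, both lower. With an estimated correlation the adjusted p was 0.973 for each. In library 16 the medians of these lists were -1.49 and -1.60, and in library 13 they were 0.19 and 0.27. Both calls were lost with background subtracted and TMM factors (adjusted p of 0.188 and 0.173), and the medians in library 16 were -0.86 and -0.96. Without library 16 both lists were higher, with adjusted p of 0.00379 and 0.00126. Mki67, a marker of dividing cells, was at 582.1 ± 165.5 (SD, n = 3) in the controls, 1150.91 in library 13 and 279.09 in library 16. With background subtracted and TMM factors it was at 615.07, 606.24 and 768.19 in the controls, 784.96 in library 13 and 251.52 in library 16. Its relative log2 change was 0.22 without library 16. Relative log2 changes were -1.35 for Top2a, 0.04 for Pola1 and -0.75 for Rrm1. Background subtraction took Pola1 from 523.64 to 34.29 in library 16, below the lowest control at 74.53.

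**Figure D2:**
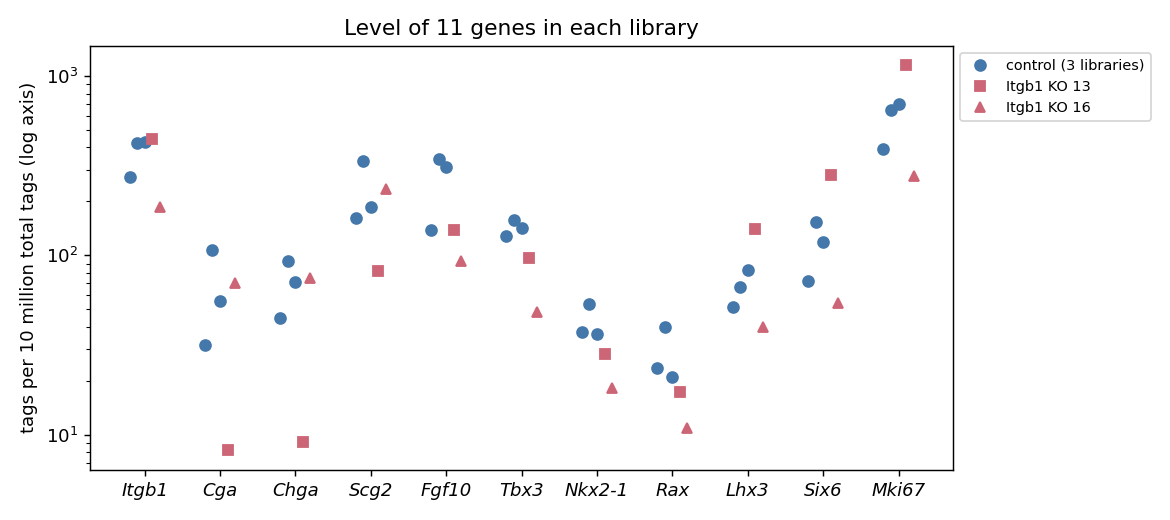
Tags per 10000000 total tags (log axis) of 11 genes, 1 point per library; circles are the 3 controls, the square is library 13 and the triangle library 16. Cga is at 8.18 in library 13 and 70 in library 16, while Six6 is at 282.73 and 54.55.

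Markers of the neighbouring hypothalamus and of neurons were lower as a set. Of 27 measured hypothalamic and neuronal genes, 16 lay below the median gene (camera, adjusted p = 0.00339). The estimated correlation gave an adjusted p of 0.973. The list's median was -0.33 in library 13 and -0.32 in library 16. Its adjusted p was 7.44e-05 without library 16 and 0.134 without library 13. It kept its call with background subtracted and TMM factors (adjusted p = 0.0331), at medians of -0.59 and -0.44. Fgf10, at the floor of 0 in library 16 on that scale, was part of this fit, which was not repeated without it. Fgf10 (mm9 chromosome 13, 119504306 to 119581380), a growth factor made by the infundibulum, was at 139.09, 344.55 and 310.91 in the controls, 138.18 in library 13 and 92.73 in library 16. Map2, a neuronal microtubule protein, had a relative log2 change of -0.74. Genes chosen after their values were seen included the transcription factors Nkx2-1 and Rax of this list. Tbx3, chosen likewise, belongs to the progenitor list and not to this one. Tbx3 was at 143.0 ± 14.1 (SD, n = 3), 97.27 and 48.18. Nkx2-1 was at 42.4 ± 9.73 (SD, n = 3), 28.18 and 18.18, and Rax at 28.2 ± 10.3 (SD, n = 3), 17.27 and 10.91. Each lay below every control in both libraries, the pattern they were chosen for, and none passed the gene test. Lhx2, from the same later choice, was at 52.7 ± 7.77 (SD, n = 3), 32.73 and 54.55, within the controls in library 16 before scaling. With background subtracted and TMM factors it was at 29.44 there, below the lowest control at 45.84.

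Matrix, mesenchymal and mechanosensitive lists were lower as sets, with lower medians in library 16 than in library 13. Interstitial matrix genes (20 of 25 below the median gene) were lower with an adjusted p of 0.00191, mesenchymal transition genes (13 of 16 below) with 0.00339, and YAP and SRF target genes (18 of 22 below) with 0.00339. None of these held with an estimated correlation (adjusted p = 0.973). Their medians were -1.13, -0.79 and -1.08 in library 16, and -0.22, -0.32 and -0.07 in library 13. Interstitial matrix kept its call with background subtracted and TMM factors (adjusted p = 0.01), at a median of -0.89 in library 16. The other two lost theirs (adjusted p of 0.261 and 0.148), with medians of -0.36 and -0.51 there. Without library 16 the adjusted p were 0.461, 0.0506 and 0.957. With background subtracted and TMM factors the medians of the 3 lists in library 13 were -0.33, -0.34 and -0.08. Mesenchymal transition genes were then about as low in both libraries. The direction of that list and of interstitial matrix thus did not rest on library 16 alone. Fbn2 and Vcan, encoding fibrillin 2 and versican, had relative log2 changes of -0.92 and -0.93. Those of Cdh2 and Cdh11 were -1.21 and -1.23, and those of Actb and Tead1 -1.07 and -0.38. FGF and ERK target genes (15 of 17 below) were also lower at an adjusted p of 0.00339, which was 0.973 with an estimated correlation, 0.968 without library 16 and 0.172 with background subtracted and TMM factors. Il17rd and Spred1, feedback inhibitors of FGF signalling, had relative log2 changes of -0.55 and -0.98.

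The lists closest to the targeted receptor did not pass the test. The 19 other integrin subunits had a median relative log2 change of 0.18 (adjusted p = 0.337), with Itga9 at -1.32 and Itgb5 at 0.01. Partners of integrins at focal adhesions had a median of -0.15 (adjusted p = 0.337), with Flna at -1.11 and the focal adhesion kinase gene Ptk2 at -0.26. Basement membrane genes had a median of -0.02 and a mean of 0.07 (adjusted p = 0.809), with Lama2 at 0.29 and Col18a1 at -0.55. Background subtraction took Lama2 from 968.18 to 16.94 in library 16, below the lowest control at 28.36. Epithelial junction and polarity genes had a median of -0.10 (adjusted p = 0.0962), with Pard3 at -0.41, and were lower without library 13 (adjusted p = 0.0157).

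Vascular lists did not pass the test. The 30 endothelial markers had a median relative log2 change of -0.03 (adjusted p = 0.62), 14 above and 16 below the median gene. Flt1 and Erg, its members of highest level, had relative changes of 0.50 and 0.69. Chosen after their values were seen, Pecam1, Cdh5 and Kdr had relative changes of 0.03, -0.04 and -0.43. Mural cell markers had a median of 0.17 and a mean of -0.03 (adjusted p = 0.871), with Notch3 at -0.49 and Pdgfrb at -0.40. Angiogenic and guidance signals had a median of 0.07 (adjusted p = 0.987), with Angpt1 at -0.19 and Efnb2 at -0.59. Hypoxia and glycolysis genes had a median of -0.24 (adjusted p = 0.225), with Kdm3a at -0.75 and Ldha at -0.48. They were lower without library 13 (adjusted p = 0.0318) and higher without library 16 (adjusted p = 0.0263). Erythroid markers had a median of 0.17 (adjusted p = 0.871), with Hba-x at -0.53 and Sptb at 0.89, and were lower without library 16 (adjusted p = 0.0068).

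Markers of 2 other tissues were higher as sets. Oral and surface epithelium genes (15 of 19 above the median gene) had an adjusted p of 0.00752 and skeletal muscle genes (18 of 19 above) one of 0.00456. With an estimated correlation both had an adjusted p of 0.973. Their medians were 0.92 and 0.73 in library 16 and 0.30 and 0.26 in library 13. Both kept their calls with background subtracted and TMM factors, in the fit of both knockout libraries (adjusted p of 0.00975 and 0.00396). Their medians in library 16 were then 1.80 and 1.84. That fit kept genes with a mean of at least 5 over all libraries, so a gene could pass by its level in library 16 alone. Whether this raised the medians there was not tested. On that scale the medians in library 16 were also 1.93 for interferon genes, 1.90 for erythroid, 1.60 for macrophage and 1.09 for mural cell markers. They were 1.07 for neural crest, 0.99 for integrin subunits and for WNT targets, and 0.86 for endothelial markers. Progenitor and cell cycle lists lay below the median gene there. None of these higher lists, oral epithelium and muscle apart, passed in that fit, and library 16 was not tested alone on that scale for them. Without library 16 the adjusted p were 0.157 and 0.901, and without library 13 they were 0.102 and 0.0576. The muscle list also lost its call without control library 12 (adjusted p = 0.0662). Shh and Esrp1 had relative log2 changes of 0.76 and -0.18, and Ttn and Myl4 of 0.56 and 0.16. The region kept for Shh ran from 28794324 to 29045749 on mm9 chromosome 5, and most of its tags were background. Subtraction took it from 505.45 to 128.73 in library 16, still the highest, and from 80 to 14.90 in control library 9. Ttn went from 520.91 to 104.72 in library 16, below control library 10 at 116.39. No member of any list passed limma over all genes. Adjusted over the list alone, 9 oral epithelium genes and 8 basement membrane genes passed, 4 angiogenic signals, and 3 each in the muscle and pituitary differentiation lists. The same count was 2 for integrin subunits, erythroid, neural crest, WNT and morphogen lists, 1 for progenitor, BMP, Hedgehog and interferon lists, and 0 in the others. These counts include the shift of all genes.

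Of the other marker lists none passed. Median relative log2 changes were 0.26 for macrophage markers (adjusted p = 0.809), -0.11 for head mesenchyme (0.225 adjusted p), 0.08 for cartilage (0.946 adjusted p) and 0.23 for neural crest and glia (0.337 adjusted p). Emr1 and Ptprc had relative changes of 0.53 and 0.60, and Foxp2 and Tbx15 of -0.33 and -0.23. Those of Sox6 and Sox5 were -0.34 and -0.25, and those of Mitf and Ednrb -0.05 and -0.39. Background subtraction took Emr1 from 233.64 to 47.78 in library 16, still the highest, and Ptprc from 165.45 to 0. Macrophage markers were lower without library 16 (adjusted p = 0.0161).

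Signalling and stress lists did not pass either. The adjusted p was 0.0915 for NOTCH genes (median -0.26; 0.0157, lower, without library 13), 0.269 for BMP and TGFb targets (median -0.27), 0.531 for WNT targets (median 0.15) and 0.429 for Hedgehog targets (median -0.21). It was 0.896 for morphogen ligands and antagonists (median 0.15), 0.451 for p53 targets (median -0.18), 0.62 for immediate early and heat shock genes (median -0.16) and 0.0915 for interferon and antigen presentation genes (median 0.44). Relative log2 changes were -0.56 and -0.60 for Notch2 and Notch1, -1.01 and -0.11 for Skil and Smad6, and 0.07 and -1.38 for Znrf3 and Ccnd1. They were -0.98 and 0.81 for Ptch1 and Nkx2-2, -0.54 for Dkk2, and -0.01 and -0.18 for Apaf1 and Sesn1. For Hsph1 and Dnajb1 they were -0.67 and -0.85, and for B2m 0.28. Background subtraction took Nkx2-2 from 352.73 to 132.77 and B2m from 149.09 to 51.27 in library 16, where both stayed the highest. Sex-linked transcripts (adjusted p = 0.62; 0.0244, lower, without control library 10) differed between embryos. Xist was at 2089.09 in control library 10 and at most 204.55 in the others, while the Y-linked gene Uty was at 24.55 there, 168.18 and 364.55 in control libraries 9 and 12, and 437.27 in library 13. Uty was at 119.09 in library 16, which did not exceed the background estimated there from autosomal genes, as subtraction left 0.

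**Figure D3:**
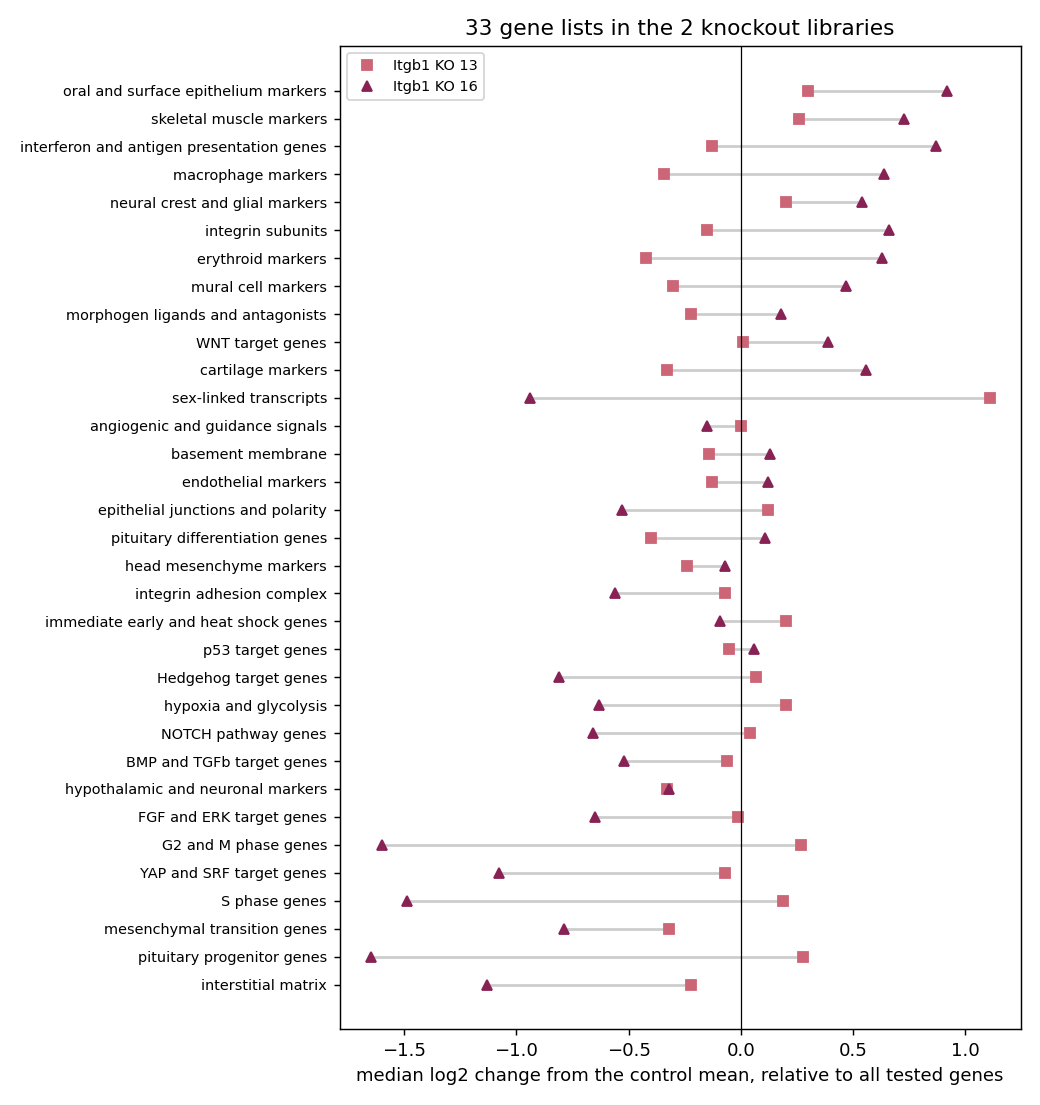
Median log2 change from the control mean, relative to all tested genes, for 33 gene lists; squares are library 13 and triangles library 16. Pituitary progenitor genes lie at 0.28 and -1.65, hypothalamic and neuronal markers at -0.33 and -0.32.

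The authors' deposited table lists 1140 genes, 643 higher and 496 lower in the knockout. Itgb1 is listed there 0 times. The deposited log2 change is that of its genotype values, and the libraries behind these are not stated. They did not follow the levels used here: over 1022 symbols also tested, the Spearman rho was 0.07 between the control value and the control mean and 0.12 for the knockout. Of these symbols, 597 (58.4%) had the same direction relative to the median gene, 260 of 571 higher and 337 of 451 lower ones. Across these genes the log2 changes of both sources had a Spearman rho of 0.22. As limma called 0 genes, the overlap with the authors' deposited table was 0, and 0 is also what independent lists would share.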

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

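All tests in this part were chosen after the results were seen. Tags over silent receptor genes, which belong to none of the fixed gene lists, had a density of 1.50 per kilobase in library 16. It was 0.48 in library 13, and per total tags both lay above the highest control at 0.40. Unspliced RNA of transcribed genes does not account for tags over silent genes (1.50), and a single scaling factor does not either, since the 200 densest genes moved by -1.16 on the log2 scale while the silent genes moved by 2.47. Background that does not depend on transcription, such as genomic DNA, may be the source, at 3.78 times the highest control, and no test here identified the material. Whether the knockout itself contributes is open with 2 libraries. Library 13 was at 1.21 times the highest control, control library 10, but only per total tags. The TMM factor was 0.92 in control library 10, 1.22 in library 13 and 1.63 in library 16. Divided by these factors, library 13 is no longer above control library 10, and library 16 still is, by less.

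Cga, Chga and Scg2 were lower in library 13 than in library 16. Background does not hide a fall as large in library 16. With it subtracted, the 3 genes had a median log2 ratio to the control mean of -0.15 there, and of -0.26 with TMM factors too. On that last scale each was above its ratio in library 13 by more than the range of the controls. A smaller fall in library 16 stays open. Chga lay below the lowest control with TMM factors (63.47 against 67.00), from 82 reads. Relative to the median gene the fit without library 13 gave a median of -1.12 over the 3 genes, but that median gene was itself 1.28 higher. With background subtracted and TMM factors, the ratios of -0.33, -0.26 and -0.12 were smaller than the log2 range of the controls (1.10, 0.35 and 0.64). Fewer pituitary cells in library 13 would lower progenitor genes by as much, but their median was 0.28, before and after background subtraction with TMM factors. The lower quartile was -0.08 and the lowest member -1.66 on that scale, where the 3 genes had ratios of -5.58 to -2.23. A less advanced stage of that embryo may fit, as the G2 and M phase list was also higher (0.27). An effect of the knockout present in 1 embryo stays open as well, because nothing in the labels separates the embryos.

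Hypothalamic genes were lower as a set at the preset correlation, and not with an estimated one (adjusted p = 0.973). The call held without library 16 and was lost without library 13 (adjusted p = 0.134). For library 13 a median raised by background does not explain this, since the list stayed lower with an adjusted p of 9.93e-05, at the preset correlation, after subtraction and TMM scaling. For library 16 this stays open. The list made no call there before subtraction, nor after it without Fgf10, which fell to the floor of 0 (adjusted p = 0.594). The list median there was -0.32 over 27 members before and -0.39 over 20 members after, without Fgf10. These medians are not over the same genes, and the members spread far more widely than that. Less adjacent neural tissue in the dissection is possible too. On the subtracted and scaled values the regional members had a median of -1.01 in library 13 (8 of 10 below 0) and -0.67 in library 16 (7 of 10 below 0, from -7.91 to 2.86). In library 13 most neuronal members were lower too, with a median of -0.41 (9 of 11 below 0), as less neural tissue would give. In library 16 they were split, with a median of -0.25 (6 of 11 below 0, from -2.33 to 1.81). The test asked for lower neuronal members in both libraries, so it could not tell. An effect of the knockout on the infundibulum also remains untested.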

How the results depend on the processing

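The alternatives with background subtracted, TMM factors in limma, edgeR quasi-likelihood tests, a sex covariate and fry with library medians removed were chosen after seeing the data. A change of direction was counted for lists and single genes where either fit made a call. For causes not shown by the construction of an alternative, the cause was not tested. The count of changed genes was 0 with limma under every other planned filter, factor and pseudocount and without each library. It was 2685 at an adjusted p under 0.1 and 25 with DESeq2 (5 of them in the authors' deposited list). With background subtracted it was 1 (Impg1, chosen after its values were seen). With TMM factors and a mean of at least 5 also, it was 0. With library 16 also left out it was 3 (Chga, Cga and Tshr). The edgeR quasi-likelihood test gave 0 genes with all libraries, 3 without library 16, 6134 without library 13 and 0 without each control. The relative log2 change of Itgb1 stayed below 0 in every fit, from -2.26 without library 13 to -0.53 without library 16. This does not set Itgb1 apart. In the main fit Itga9 was at -1.32 and Top2a at -1.35, while others such as Ptk2 were at -0.26. Itgb1 was not compared with genes of like level as a set. Of 86 other named genes, 37 changed sign relative to the median gene in at least 1 alternative, none past the threshold in either fit.

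The 10 lists past the threshold became 0 with an estimated correlation (adjusted p 0.973 for each), 0 with fry with or without library medians removed, and 4 with background subtracted, with or without TMM factors. The number of calls was 7 to 11 with each library left out, but without library 16 only 1 of the 10 lists (hypothalamic) kept its call and direction, 2 turned and 4 calls were not there before. Without library 13, 7 of the 10 kept call and direction, without control 12 it was 9, and without control 9 or 10 all 10. In fry without centring the shift of all genes turned 8 lists upward, at adjusted p of 0.292 (interstitial matrix), 0.499 (progenitor), 0.247 (hypothalamic), 0.342 (S phase), 0.441 (G2 and M phase), 0.267 (FGF), 0.251 (YAP and SRF) and 0.291 (mesenchymal transition). Oral epithelium and muscle had 0.214, and with medians removed all 10 had 0.798.

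With background subtracted the adjusted p were 0.123 (progenitor), 0.154 (S phase, and G2 and M phase), 0.056 (FGF), 0.21 (YAP and SRF) and 0.192 (mesenchymal transition). With TMM factors also they were 0.172 (progenitor and FGF), 0.188 (S phase), 0.173 (G2 and M phase), 0.148 (YAP and SRF) and 0.261 (mesenchymal transition). With library 16 also left out, lists turned at 0.0213 (basement membrane, lower), 0.018 (hypoxia, higher), 0.0113 (erythroid, lower), 0.0997 (progenitor, higher), 0.0282 (cartilage, lower), 0.00252 (S phase, higher), 0.000311 (G2 and M phase, higher) and 0.0198 (immediate early, higher). Mural cell markers (0.0286) and pituitary differentiation genes (5.83e-08) became calls there. Oral epithelium (0.0566), muscle (0.0997), FGF (0.688) and YAP and SRF (0.416) lost theirs. Hypothalamic, interstitial matrix and mesenchymal transition genes kept call and direction in that fit, at median relative log2 changes of -0.60, -0.33 and -0.34. Without subtraction and TMM factors, only the hypothalamic list had done so with library 16 left out. RLE factors made interferon genes a call (0.0268), and no filter did so for pituitary differentiation genes (0.0205).

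With each library left out in turn, adjusted p ran from 0.00044 to 0.461 for interstitial matrix, 0.0263 to 0.525 for hypoxia, 0.0068 to 0.852 for erythroid, 0.0161 to 0.911 for macrophage, 1.42e-07 to 0.461 for progenitor and 2.7e-08 to 0.905 for pituitary differentiation genes. The ranges were 7.44e-05 to 0.134 for hypothalamic, 0.00703 to 0.157 for oral epithelium, 0.00248 to 0.901 for muscle, 1.08e-05 to 0.0238 for S phase and 1.53e-07 to 0.0238 for G2 and M phase genes. They were 0.00278 to 0.968 for FGF, 0.0157 to 0.246 for NOTCH, 0.00215 to 0.957 for YAP and SRF, 0.0157 to 0.525 for junction, 0.00147 to 0.0506 for mesenchymal transition and 0.0244 to 0.968 for sex-linked genes. Of 495 list fits, 413 gave the same direction and side of the threshold, or no call in either fit. No paired analysis was possible because the groups share no embryo numbers. A sex covariate gave 0 changed genes and 11 lists whether control 10 alone or also library 16 was coded as the other sex. It made sex-linked genes (0.0244) a call in the first coding, which amounts to leaving out control 10, and pituitary differentiation genes (0.00768) in the second.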

Other observations

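Besides Rn45s, DESeq2 called 24 genes, all lower in the knockout libraries, among them Lars2, Zc3h7a, Camk1d, Gphn and Cd44, chosen after their values were seen. Lars2 was at 174369.09 tags per 10000000 in control library 12 and 61069.09 in library 16. In 23 of the 24 the ratio to Rn45s within a library spanned less than 2-fold over the 5 libraries, against 9 of 505 other genes at such levels (1.8%). The tags of Rn45s and of these genes count in the total that every value refers to. Leaving out Rn45s alone took the median log2 change of the tested genes from 0.97 to 0.83, and no fit left out the others.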
